A study of Drosophila melanogaster with 5 samples.

How the data were processed

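Total RNA from eye-antennal imaginal discs, the larval epithelia that form the adult eye, antenna and head, was labelled with biotin and hybridised to expression arrays, per the labels. Larvae of the third instar were dissected. Tumor clones were made and marked with GFP by MARCM, a method that produces marked mutant clones in an otherwise unmarked animal. The RNA was described as coming from tumors, or from discs for the control. The labels' titles gave 5 groups, each with 1 array: WT control discs, tumors with Ras overexpression alone, tumors of Sras mutant 1 with Ras, tumors of Sras mutant 2 with Ras, and tumors of a scrib mutant with Ras, which the design text names as the positive control. The Sras mutants are 2 separate groups in the design text and were not treated as replicates.

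The authors deposited 1 table of log2 values with 18952 probe sets per array. How the authors made these log2 values (background correction, normalization and summary of probes) is not given in the sources used here, and the log2 scale was read from the values themselves, which ran from 3.32 to 14.9. No scanner intensities were used here. The number of arrays limits the precision: with 1 array per group there are no replicates, so no test, p-value or error of a mean was computed, and every difference compares single arrays and not conditions.

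Array medians of the deposited values ran from 5.92 in the scrib array to 6.07 in the WT control array. Their largest gap, 0.153 log2, exceeded the limit of 0.1 set before the data were examined, and by that rule the 5 arrays were quantile normalized. Quantile normalization gives every array the same distribution of values, so a shift of most genes in one direction cannot be seen afterwards. Of the probe sets, 183 were controls, 13646 had exactly 1 gene symbol in the platform annotation, 402 had several symbols, and 4720 others were unnamed here. Symbols were updated through gene identifiers in a table of the Release 6 assembly of the fly genome, which held 13543 of the probe sets with 1 symbol. No coordinates were used. The probe set with the highest mean represented each gene, and 1094 genes had more than 1 probe set. Genes were kept where the highest of the 5 values reached the 40th percentile of all gene values (6.36), which left 7850 of 11981 genes.

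Genes at least 2-fold apart (an absolute log2 difference of 1 or more) were counted for each comparison. For 37 gene lists fixed before the data were examined, the median log2 difference was set against 10000 random lists of the same size, matched on mean expression in 10 bins. A list was called set apart below the 2.5th or above the 97.5th percentile, which describes these arrays and is not a test. Of 708 list members, 150 had no named probe set. Several genes stand in more than 1 list, so the lists are not independent. Named genes were chosen by a rule fixed in advance: per main comparison the 8 highest and 8 lowest genes with a symbol other than a CG or CR number, up to 2 highest and 2 lowest genes of each list described, every measured gene of the Fanconi list, the 5 highest and 5 lowest between the Sras mutants, and Sras, scrib and Ras85D. Ras85D was not analysed here because no probe set was named for it. For comparisons of both Sras mutants, genes were ranked by the smaller of the 2 differences.

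The comparisons against Ras share 1 array. Overlaps were therefore set against 100 simulations of unchanged arrays sharing a control, with noise taken from the difference between the Sras mutants, and against the overlap of independent lists. The counting was tested on simulated data, with noise from the same difference, for both Sras mutants minus Ras over 7850 genes. There 98% of genes changed by 1.5 log2 and 100% of those changed by 3 log2 were recovered, and 20 of 7650 unchanged genes were counted. In the same test for Sras mutant 1 minus Ras, 4% of unchanged lists of 15 genes and 100% of lists shifted by 0.5 log2 were set apart. Those lists were random genes with independent noise, so the 4% does not carry over to lists whose genes move together. Between the Sras arrays, the closest pair, 6 of the 37 fixed lists were set apart higher and 15 lower.

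The alternatives planned before the data were examined were centring each array on its median, no filter on dim genes, a stricter filter (mean at or above the 50th percentile), the mean of a gene's probe sets, and thresholds of 1.5-fold and 3-fold. After the data were seen, 3 were added: the values as deposited, each array centred on the median of 20 eye and antennal identity genes (the kept genes of the retinal determination list and of the antennal and head list), and the WT control array as the baseline in place of Ras. The identity genes are not a neutral reference. The 8 kept retinal determination genes among them were set apart above Ras in both Sras arrays, and Antp, which was lower there, is also a member. Computations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.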

Results

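Gene expression was measured in eye-antennal discs and disc tumors of Drosophila larvae with 5 arrays, 1 per group, of 18952 probe sets each. The groups were WT control discs, tumors overexpressing Ras alone, tumors of Sras mutant 1 or Sras mutant 2 with Ras, and tumors of a scrib mutant with Ras. The series title places the study among work on oncogene-induced senescence and the Fanconi anemia pathway, which repairs DNA crosslinks. There were no replicates, so each difference below is between single arrays. All differences are in log2 units after quantile normalization, and paired values give Sras mutant 1 and then Sras mutant 2. As the nearest guide to the spread, the Sras arrays differed from each other with an SD of 0.243 over 7850 genes.

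The genes named in the labels were looked at first. The probe set of the gene Sras, which encodes a CAAX-box protease, read 9.19 and 9.05 in the Sras arrays, 9.56 in WT control, 9.40 in Ras and 9.65 in the scrib array. The gene scrib, a polarity gene, read 11.30 in the scrib-labelled array, against 10.56 in WT control, 10.76 in Ras, and 11.56 and 11.51 in the Sras arrays. The lesions, and whether the label Sras refers to this gene, are not given in the sources used here, so neither level checks a label. The scrib transcript was not lower in the array labelled scrib mutant than in Ras or WT control.

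The WT control and Ras arrays held high levels of transcripts of other larval tissues that were far lower in the 3 mutant arrays. Sgs3, a glue protein gene of the salivary gland, read 14.70 and 14.53 in WT control and Ras, against 6.61, 9.49 and 5.64 in Sras mutant 1, Sras mutant 2 and scrib. The median of 10 salivary gland and gut markers lay −6.41 and −4.86 from Ras in the Sras arrays and −7.19 in the scrib array, and that of 14 muscle markers lay −2.52, −2.65 and −3.11 from Ras in the same order. Fat body markers (9 genes) had medians of −2.66, −1.50 and −3.05, and neuron and glia markers (15 genes) of −0.81, −0.84 and −2.06. The neuron and glia list shares elav with the photoreceptor list of the disc, whose median was −1.87 in scrib. It therefore does not mark other tissue alone. The muscle genes Tm2 and Mlc1 lay −4.45 and −4.30 from Ras in Sras mutant 1, and Gs2, a glutamine synthetase of glia, lay −3.96. Antp, a Hox gene of the thorax, lay −3.48, −3.28 and −3.36 from Ras in Sras mutant 1, Sras mutant 2 and scrib. WT control and Ras were closer to each other in the marker lists. Ras minus WT medians were −0.14 for salivary gland and gut (set apart downward), 0.09 for muscle, 0.05 for fat body and 0.27 for neuron and glia (set apart upward). Every comparison of a mutant array with Ras below moves together with these markers. The Ras array also stood apart in its control probe sets: those near the 3′ and 5′ ends of 3 housekeeping transcripts differed by a mean of 1.35 log2 units in Ras (lowest 1.25), against 0.95 in WT control, 0.93 and 0.91 in the Sras arrays and 0.88 in scrib. Every comparison with Ras contains this array, and how far its control values carry over to other genes was not measured. Levels near or below the filter value of 6.36 are close to background, so a large difference that starts or ends there bounds the change from below, and its rank among the highest or lowest genes below is not informative.

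**Figure D1:**
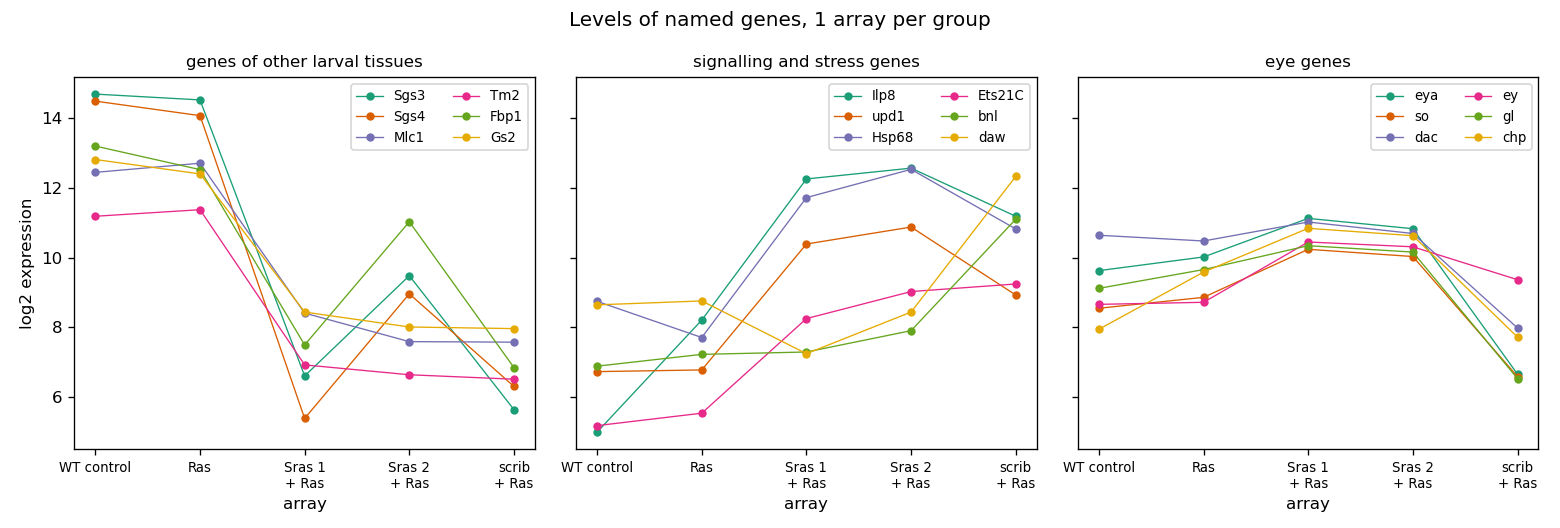
Log2 expression of 18 named genes (y axis) on each of the 5 arrays (x axis), with 1 point per array and lines that only join the points of a gene. Sgs3 sits at 14.70 and 14.53 in WT control and Ras and at 9.49 or less in the other arrays, Ilp8 and upd1 are high in the 3 mutant arrays, and eya is at 6.66 in the scrib array alone.

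The first comparison asked how tumors with Ras alone differed from control discs. Ras exceeded WT control at least 2-fold for 55 genes and lay at least 2-fold below it for 107 (36 and 179 after centring on eye and antennal identity genes, a setting chosen after the data were seen), and the arrays correlated over genes with r = 0.981 (genes are not independent replicates). The highest differences were in Jig (4.66), Ilp8 (3.21), a relaxin-like peptide gene through which discs delay metamorphosis, the serine protease genes yip7 (2.18) and Jon65Aiii (1.97), IM33 (1.80), Gnmt (1.65), chp (1.64), a photoreceptor membrane protein gene, and the cuticle gene Cpr65Ec (1.63). Of these, Jig, yip7, Jon65Aiii, IM33 and Gnmt were far lower than Ras in the Sras arrays and lower in scrib, as were the markers of other tissues. From Ras, yip7 lay at −5.09, −4.70 and −5.11 in Sras mutant 1, Sras mutant 2 and scrib. Ilp8 and chp were higher than Ras in the Sras arrays. Whether the first 5 genes differ within the disc or through other tissue was not tested. The lowest were yellow-d2 (−4.37), the prophenoloxidase genes PPO2 (−2.29) and PPO1 (−2.27) of crystal cells, the metallothionein genes MtnD (−1.91) and MtnB (−1.82), CNT2 (−1.84), Drsl5 (−1.77) and Cyp9c1 (−1.63). Ilp8 (5.00) in WT control and yellow-d2 (4.80), MtnB (5.86) and MtnD (6.26) in Ras read below the filter value. Jig (6.45) in WT control and CNT2 (6.47) in Ras lay near it, so the order of these genes is not informative.

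Of the pathway lists, EGFR, Ras and MAPK genes were set apart upward in Ras against WT control, with a median of 0.30 over 12 genes at the 99.99th percentile of random lists. Its feedback inhibitors aos and sty differed by 1.09 and 1.03, the only members past 2-fold. JNK genes (median 0.15) and antennal and head identity genes (0.18) were also set apart upward, as were polarity and junction genes (0.18), but all 3 medians were below 0 after centring on the identity genes. Wingless and Dpp targets (0.25) and neuron and glia markers (0.27) were set apart upward, with medians of 0.05 and 0.07 after that centring, when the EGFR median was 0.10. Hemocyte markers were set apart downward, with a median of −0.58 over 18 genes, 4 of them at least 2-fold lower, among them NimC2 (−1.56) and eater (−1.18). Ecdysone response genes (−0.29), proteasome genes (−0.15), trachea markers (−0.11), heat shock genes (−0.23) and salivary gland and gut markers (−0.14) were set apart downward too. So were the lysosome and secreted factor lists described further below. The Fanconi list had a median of 0.12 at the 87.6th percentile and was not set apart.

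The central comparison asked what each Sras mutant added to Ras. Sras mutant 1 exceeded Ras at least 2-fold for 317 genes and lay below it for 767, and Sras mutant 2 did so for 389 and 781. Both mutants passed 2-fold together for 280 genes upward and 703 downward. The highest were Ilp8 (4.05 and 4.36), the heat shock gene Hsp68 (4.01 and 4.82), upd1 (3.61 and 4.10), a ligand of the JAK/STAT pathway, the cytochrome P450 genes Cyp4p1 (3.55 and 4.18) and Cyp6a20 (2.94 and 3.58), spz3 (3.35 and 3.84), the tetraspanin gene Tsp42Ed (2.81 and 3.10) and the integrin gene ItgaPS4 (2.74 and 3.45), of which Cyp6a20 (4.74) and ItgaPS4 (5.23) read below the filter value in Ras. The lowest were the odorant-binding protein genes Obp56d (−8.15 and −8.89) and Obp56a (−5.49 and −5.98), the cuticle genes Lcp9 (−7.78 in mutant 1, with levels of 4.89 in mutant 2 and 12.90 in Ras) and Cpr11B (−5.75 and −5.78), Sgs5bis (−7.67 and −7.19), Vajk3 (−6.37 and −6.65), Vajk2 (−5.90 and −5.82) and nol (−5.57 and −6.33). These 8 genes read 7.05 or less in the Sras arrays, near or below the filter value, so their order is not informative. Independent lists of these sizes would share 15.7 genes upward and 76.3 downward, and simulated unchanged arrays sharing a control gave at most 20 and 22. Across genes the differences of both mutants from Ras correlated with r = 0.969 against 0.497 simulated, with a covariance of 0.928 against 0.0293. The simulated noise came from the closest pair of arrays and held no difference in RNA of other tissues. An excess over it therefore does not separate such a difference from a change shared by the mutants. A single Ras array cannot be split, so part of the excess may come from it. Centring on the identity genes gave 160 genes higher and 1005 lower for Sras mutant 1, and 146 and 1345 for Sras mutant 2.

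Several signalling lists lay above Ras. JAK/STAT genes had medians of 1.10 and 1.10 (0.79 and 0.56 after centring on the identity genes), with 4 of 7 kept genes at least 2-fold higher in both mutants, among them the ligand gene upd2 (2.56 and 3.20) and chinmo (1.95 and 1.74). Hippo targets were at 0.70 and 0.77 (0.38 and 0.22 after that centring), with kibra at 1.34 and 1.56, and Wingless and Dpp targets at 0.53 and 0.61 (0.21 and 0.07), with dpp at 1.00 and 1.14. JNK genes were at 0.30 and 0.41, set apart in mutant 2 alone (97.2nd and 99.8th percentiles), where the median was −0.13 after centring on the identity genes. Ets21C, a transcription factor gene of that list, differed by 2.71 and 3.49, and Gadd45 by 1.87 and 2.74, while the ligand gene egr lay at −0.69 and −0.76. EGFR, Ras and MAPK genes were at 0.52 and 0.54, and at 0.21 and below 0 (−0.01) after that centring, with Egfr at 0.91 and 0.95 and Ets65A at −1.80 and −2.11. Notch genes were not set apart (0.18 and 0.14). Among the 4 kept heat shock genes the medians were 1.44 and 1.82 (1.13 and 1.27 after that centring), with Hsp26 at 1.70 and 2.24.

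The Fanconi list lay above Ras with medians of 0.57 and 0.47 over 14 genes, at the 99.6th and 98.7th percentiles, but at 0.25 and −0.08 after centring on the identity genes. Differences of at least 2-fold in both mutants were seen for 2 members, PolZ1 (1.23 and 1.58), a translesion polymerase subunit gene, and PolQ (1.17 and 1.07), a polymerase of end joining. FANCI (1.00 and 0.85) and Fancd2 (0.99 and 0.81), whose products form the central complex of the pathway, were close to 2-fold, followed by Fancm (0.77 and 0.93), Snm1 (0.67 and 0.62), Rev1 (0.60 and 0.52), Ercc1 (0.54 and 0.32), Fancl (0.52 and 0.37), mei-9 (0.51 and 0.42) and Brca2 (0.49 and 0.41). Blm (0.11 and 0.07), Usp1 (0.01 and −0.11) and mus81 (−0.24 and −0.21) lay near or below Ras. In the scrib array the median was 0.80, with PolZ1 at 1.67, PolQ at 1.42, FANCI at 1.21 and Fancm at 1.03. Against scrib, the Sras arrays had Fanconi medians of −0.16 and −0.10 and were not set apart.

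Other DNA repair and growth lists lay above Ras as well. Homologous recombination and DNA damage response genes had medians of 0.79 and 0.75 (0.48 and 0.20 after centring on the identity genes), with 7 of 19 at least 2-fold higher in both mutants, led by the end-joining genes Ku80 (1.64 and 1.84) and Irbp (1.52 and 1.71). Genes of the p53 and irradiation list were at 1.07 and 1.19 (0.75 and 0.64 after that centring), with 6 of 11 at least 2-fold higher, while skl, a cell death gene, lay at −1.32 and −1.75. Ku80, Irbp, RnrL and Ilp8 are among these 6 and also stand in other lists described here, so the p53 list is not separate from those. DNA replication (0.53 and 0.43), mitosis (0.47 and 0.33), ribosome biogenesis (0.58 and 0.53) and polarity and junction genes (0.40 and 0.47) were set apart upward, and after that centring their medians were 0.21, 0.15, 0.26 and 0.09 in mutant 1 and below 0 in mutant 2. In these lists RnrL differed by 1.21 and 1.22, feo by 1.01 and 0.93, l(1)G0020 by 0.90 and 0.82, and shg by 0.83 and 0.87. Cell death genes were not set apart (0.03 and 0.06).

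Both eye lists had medians above Ras in the Sras arrays. Retinal determination genes had medians of 1.26 and 1.18 (0.95 and 0.64 after centring on the identity genes, to which they belong), with 5 of 8 at least 2-fold higher in both, among them ey (1.73 and 1.59) and Optix (1.37 and 1.37), and tsh near 0 (−0.18 and −0.01). Photoreceptor and furrow genes were at 0.56 and 0.46, set apart upward, with 3 of 19 at least 2-fold higher in both mutants and 1 lower, and their medians were 0.24 and −0.09 after that centring; lz was at 1.42 and 1.33, ato at 1.35 and 1.43, and pros at −1.41 and −1.51. Antennal and head identity genes were not set apart (0.38 and 0.38), though ss differed by 1.70 and 1.90. Antp, named above as far lower than Ras, also stands in this list. Glutathione genes (0.28 and 0.41) and unfolded protein response genes (0.30 and 0.44) were set apart in mutant 2 alone, where both medians were below 0 after that centring. GstE6 differed by 2.26 and 2.24. Ecdysone response genes were set apart downward in mutant 1 (−0.44) and not in mutant 2 (−0.13), and Edg91 lay at −3.70 and −3.53. Hemocyte markers (−0.23 and −0.43) and proteasome genes (−0.04 and −0.07) were set apart downward. Glycolysis (−0.04 and 0.13), mitochondrial respiratory chain (0.12 and 0.04), extracellular matrix (0.21 and 0.22), cytoskeleton (0.07 and 0.14) and trachea lists (0.35 and 0.26) were not set apart, although the muscle LIM gene Mlp60A of the cytoskeleton list lay at −4.16 and −4.72, and Tig of the matrix list at 1.76 and 2.15.

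**Figure D2:**
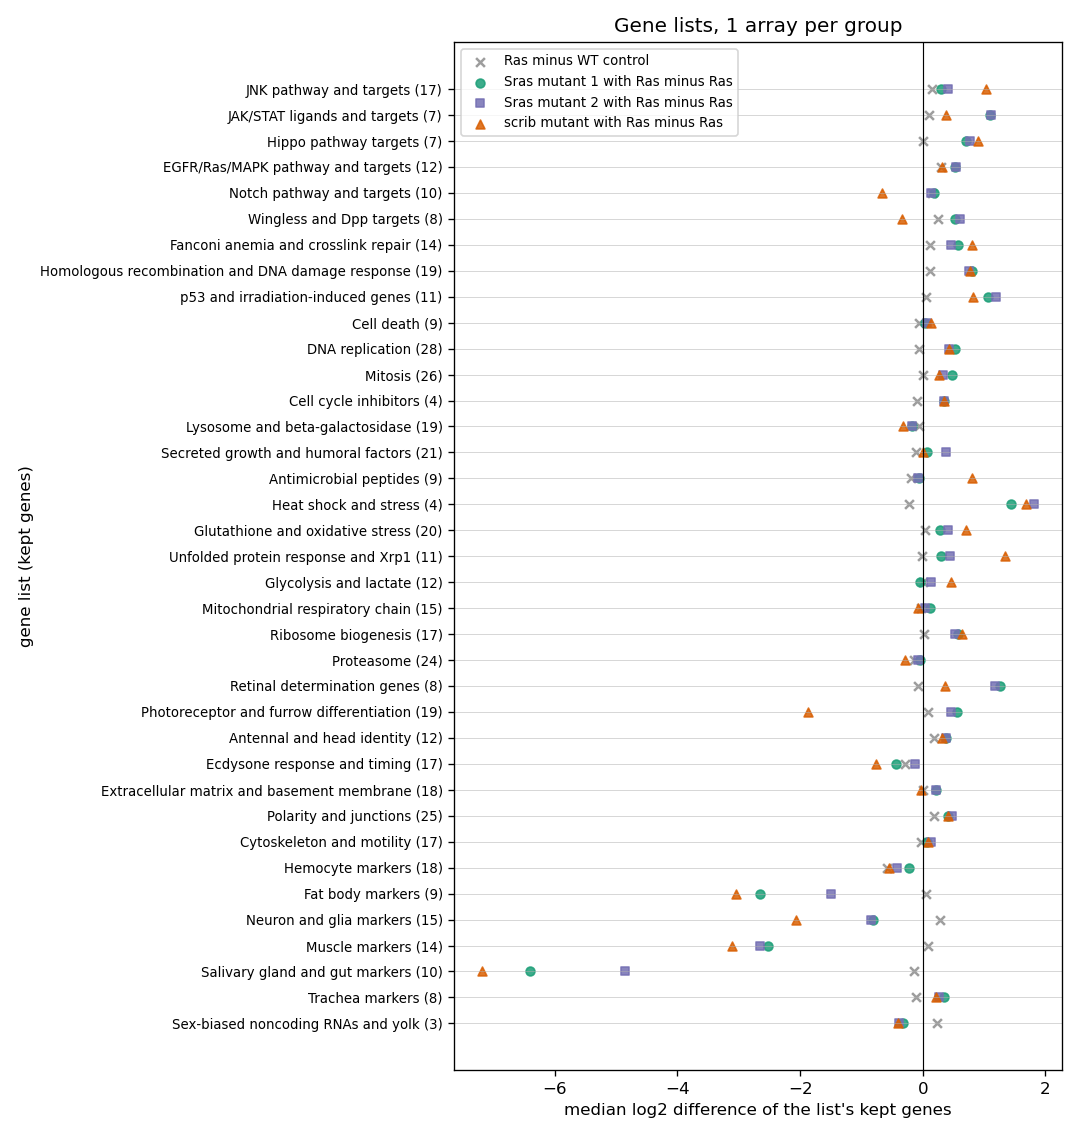
Median log2 difference of each of the 37 gene lists (x axis) for Ras minus WT control and for each of the 3 mutant arrays minus Ras, with 1 symbol per comparison and the number of kept genes in parentheses. Salivary gland and gut, fat body and muscle markers lie farthest to the left in the mutant arrays, and photoreceptor genes lie at −1.87 in the scrib array against 0.56 and 0.46 in the Sras arrays (the last −0.09 after centring on the identity genes).

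The scrib mutant with Ras, the positive control of the design, was set against the same Ras array. It exceeded Ras at least 2-fold for 727 genes and lay below it for 1111. The highest were Cyp6a20 (4.44), Tektin-C (4.19), the FGF ligand gene bnl (3.88), Ets21C (3.71), the glutathione transferase gene GstE5 (3.62), spz3 (3.59), the cuticle gene Cpr64Ac (3.58) and the activin-like ligand gene daw (3.57). Cyp6a20 (4.74), Tektin-C (4.48) and Ets21C (5.54) read below the filter value in Ras, so their differences are bounds and their rank is not informative. The lowest were the glue genes Sgs8 (−8.99), Sgs3 (−8.88), Sgs7 (−8.79), Sgs5 (−7.89) and Sgs5bis (−7.80), with Obp56d (−8.84), Lcp9 (−7.88) and the ecdysone-inducible gene ImpE2 (−8.09). Sgs5 read 6.54 in scrib and the others less than the filter value, so these differences are bounds and their order is not informative; Sgs7 read 14.81 in both Ras and WT control, at the top of the arrays. JNK genes had a median of 1.03, with 9 of 17 at least 2-fold higher, among them Gadd45 (3.35) and Pvf1 (2.80). Unfolded protein response genes were at 1.34 (Sil1 1.90, Ero1L 1.76), Hippo targets at 0.91 (kibra 2.47, ex 1.71), glutathione genes at 0.71 (GstD5 3.30) and glycolysis genes at 0.46 (Pfk 1.93, Hex-A 1.77). Heat shock (1.68), homologous recombination and damage response (0.77), p53 and irradiation (0.81), DNA replication (0.43), ribosome biogenesis (0.65) and polarity genes (0.41) were set apart upward, whereas mitosis (0.26), JAK/STAT (0.38) and EGFR, Ras and MAPK genes (0.31) were not. Even so, 3 of 7 JAK/STAT genes were at least 2-fold higher in scrib, among them upd1 (2.15), and 0 were 2-fold lower. Against scrib, the JAK/STAT median was 0.26 in Sras mutant 1, not set apart, and 0.44 in Sras mutant 2, set apart upward. Both were below 0 after centring on the identity genes.

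Photoreceptor and furrow genes had a median of −1.87 in scrib against Ras, with 14 of 19 at least 2-fold lower, among them gl (−3.13) and nrv3 (−3.06). Retinal determination genes were not set apart by their median (0.36), but eya (−3.36), dac (−2.50) and so (−2.27) were far lower, and eyg (1.01) and toy (1.01) were higher. Antennal and head genes (0.31) also went both ways, with danr at −2.69, dan at −2.25, Lim1 at 1.53 and oc at 1.46. Wingless and Dpp targets were not set apart (−0.34; bi −2.61). Notch genes (−0.66), ecdysone response genes (−0.76), hemocyte markers (−0.55) and proteasome genes (−0.29) were set apart downward, and all 4 medians were above 0 after centring on the identity genes. Because several identity genes were themselves lower in the scrib array by over 2 log2 units, that centring lifts the whole array: it gave 3496 genes higher and 700 lower than Ras.

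Of the 280 genes higher in both Sras mutants, 161 (57.5%) were also at least 2-fold higher in scrib, and 11 were at least 2-fold lower there. Of the 703 lower genes, 623 (88.6%) were also lower in scrib, and 6 were higher. After centring on the identity genes the counts were 102 of 116 higher and 551 of 985 lower. That centring lifts the whole scrib array by construction, which favours shared higher genes over shared lower ones. It therefore cannot decide which direction was shared more. Independent lists would share 25.9 and 99.5 genes, and simulated unchanged arrays at most 20 and 22. The covariance with scrib over genes was 0.943 for mutant 1 (r = 0.771) and 0.954 for mutant 2 (r = 0.778), against 0.0293 simulated. The shared Ras array may add to this excess, and so may RNA of other tissues, which the simulation left out.

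**Figure D3:**
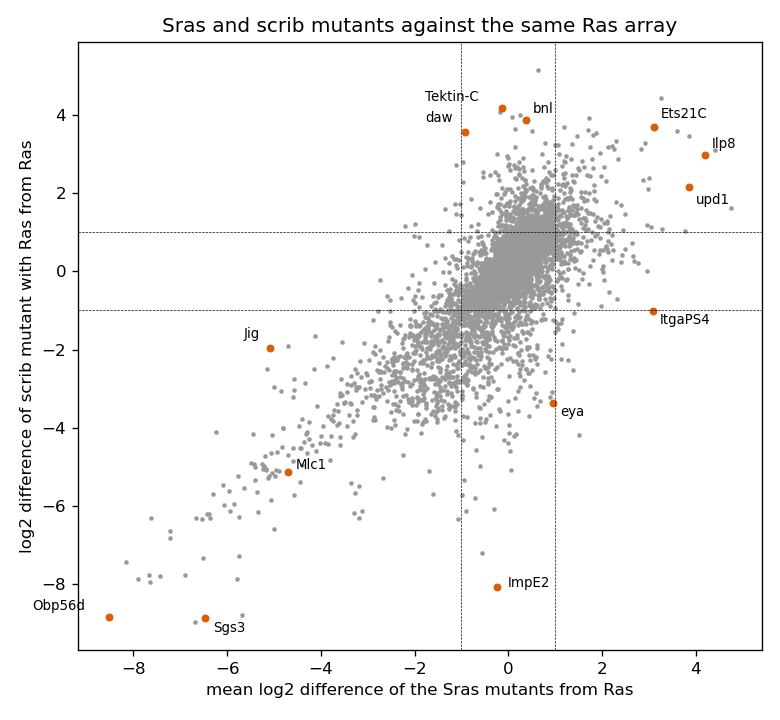
Each of the 7850 kept genes by its mean log2 difference of the Sras mutants from Ras (x axis) and its log2 difference of the scrib mutant from Ras (y axis), with dashed lines at 1 and −1 and 13 named genes in orange. Glue and muscle genes lie at the lower left, Ilp8, upd1 and Ets21C at the upper right, and ImpE2 and eya are low in scrib alone.

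A direct comparison of the Sras arrays with scrib did not use the Ras array. Both Sras arrays exceeded scrib at least 2-fold for 562 genes and lay below it for 297, counts that became 121 and 4861 after centring on the identity genes. The highest were ImpE2 (7.64 and 8.07), Peritrophin-15b (5.94 and 5.59), Peritrophin-15a (5.45 and 4.85), Spn43Aa (5.12 and 5.41), the mucin gene Muc96D (4.74 and 5.75), Ir76a (4.25 and 4.41), eya (4.47 and 4.17) and obst-J (4.17 and 4.52). In scrib, ImpE2 (5.00), Spn43Aa (5.48), Muc96D (5.30), Ir76a (4.80) and obst-J (5.03) read below the filter value, so the order is not informative. The lowest were Tektin-C (−4.44 and −4.24), daw (−5.08 and −3.89), Cyp4e3 (−3.29 and −3.20), bnl (−3.81 and −3.20), Jig (−3.13 and −3.13), Cpr64Ac (−3.06 and −3.09), eg (−2.94 and −2.96) and JhI-26 (−2.92 and −3.23), of which Tektin-C, Cyp4e3, Jig and eg read below the filter value in both Sras arrays. Photoreceptor genes had medians of 2.21 and 1.98 (1.09 and 0.64 after centring on the identity genes), with 17 of 19 at least 2-fold higher in both, led by gl (3.81 and 3.63) and chp (3.12 and 2.91). JNK (−0.69 and −0.22), unfolded protein response (−0.75 and −0.63), glutathione (−0.44 and −0.38) and glycolysis genes (−0.45 and −0.28) were set apart downward. Retinal determination (0.83 and 0.76), Notch (0.53 and 0.59), Wingless and Dpp (0.85 and 0.82), ecdysone response (0.34 and 0.46) and heat shock genes (0.58 and 1.09) were set apart upward, and all these medians were below 0 after centring on the identity genes. Tissue markers differed here too. Salivary gland and gut markers were at 0.53 and 2.03, but at −0.03 in mutant 1 with no filter on dim genes, and at −0.58 and 0.69 after that centring. Neuron and glia markers (0.91 and 0.77) and fat body markers (0.38 and 0.96) were set apart upward in both, and muscle markers in mutant 1 (0.42 and 0.14), with medians below 0 after that centring.

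The Sras mutants were also compared with each other. Their arrays correlated over genes with r = 0.991, and mutant 1 exceeded mutant 2 at least 2-fold for 14 genes and lay below it for 39, of which 8 were salivary gland, gut, fat body or muscle markers; after centring on the identity genes the counts were 32 and 26. Mutant 1 was higher in Muc11A (3.66), Nplp2 (1.64), spok (1.51), an ecdysone synthesis gene, Scp2 (1.39) and mthl6 (1.26). Whether spok differs within the disc or through other tissue was not tested. It was lower in Sgs4 (−3.57), the fat body gene Fbp1 (−3.53), Sgs7 (−3.26), Sgs5 (−2.94) and Sgs3 (−2.88). Salivary gland and gut markers had a median of −1.73 and heat shock genes of −0.40 (−1.51 and −0.18 after that centring). Hemocyte markers were higher in mutant 1 by a median of 0.22, with PPO1 at 1.25 and PPO2 at 1.19. DNA replication (0.13) and mitosis genes (0.13) were also set apart upward in mutant 1, both at 0.36 after centring on the identity genes. Of the 37 lists, 6 were set apart higher in mutant 1 and 15 lower. Against Ras, 14 were set apart higher and 8 lower in mutant 1, and 18 and 7 in mutant 2. A list can thus be set apart with a median close to 0, such as −0.05 for JNK genes between the Sras mutants.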

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

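Of the tests in this part, only the one of the Ras array by itself had its outcome stated before the result was seen; the other 5 tests were chosen after the pattern they bear on was seen.

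Photoreceptor and furrow differentiation genes moved in opposite directions from Ras in the mutants: medians of 0.56 in Sras mutant 1 and 0.46 in Sras mutant 2 against −1.87 in the scrib mutant. After centring on the identity genes the medians were 0.24, −0.09 and −1.07 in the same order, so the opposite direction held for mutant 1 and not for mutant 2 under that setting. The difference between them was not tested, since each group has 1 array. Data outside the named genes also held differences: of 1260 probe sets without a single gene name, 52 (4.13%) were at least 2-fold higher in both Sras mutants than in both WT control and Ras and 80 (6.35%) lower, against 3.15% and 7.68% of the named genes, so their shares do not set them apart from the named genes.

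The 623 genes lower than Ras in both Sras mutants and in scrib form the first pattern weighed. RNA of other larval tissues in the Ras and WT control arrays is a candidate explanation: 23 of 33 kept salivary gland, gut, fat body and muscle markers (69.7%) were among these genes, against 7.94% of all kept genes. None of the 33 stands in another fixed list, how many the disc itself expresses was not measured, and Sgs3, Mlc1 and Fbp1 read 14.53, 12.72 and 12.53 in Ras. A difference in larval stage stays open for the muscle genes, since no value here shows how their levels change with stage. For the glue genes, which are themselves switched on by ecdysone, stage and dissection cannot be told apart: the ecdysone list lay between −0.76 and −0.13, and the last value decides for neither. Genotype stays open, untested.

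The 280 genes higher than Ras in both Sras mutants form another pattern. The Ras array did stand apart in its control probe sets (a mean 3′ minus 5′ difference of 1.35, against 0.88 to 0.95 in the other arrays), so part of each difference from Ras may come from it. As the cause of the whole pattern the Ras array by itself is argued against, since 88.2% of these genes (247) were also at least 2-fold higher in both mutants than in WT control, whose control probe sets differed by 0.95; for the rest it stays open. A lower share of disc RNA in the Ras array could lift disc genes by a common amount, of which the largest difference among the identity genes (ss, 1.70) was taken as the limit. It was exceeded by 71 genes (25.4%), and 209 genes lay at or below it. The 280 genes were selected for large differences and the 20 identity genes were not, so this share cannot decide for or against dilution. Dilution stays open for all 280 genes. An effect of the Sras mutants is a hypothesis that these arrays did not test.

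Fanconi genes higher than Ras in both Sras mutants form the last pattern. Their median difference from Ras exceeded the median difference of the identity genes (0.56 and 0.67 in mutants 1 and 2) by 0.0023 in mutant 1 and differed by −0.20 in mutant 2. Centring uses another reference, the median level of the same genes on each array, and gave Fanconi medians of 0.25 and −0.08, so the outcome in mutant 1 depends on the reference, and a lower share of disc RNA in the Ras array and a difference within disc cells cannot be told apart. More RNA from cycling cells is also a candidate explanation: the Fanconi median lay within 0.038 of the DNA replication median in both mutants, with the replication list set apart upward. Photoreceptor and furrow genes (0.56 and 0.46) lay closer still to the Fanconi medians, so such a match does not single out cycling cells. In scrib the match was absent, with medians of 0.80 for Fanconi and 0.43 for DNA replication genes. A specific response of the Fanconi pathway to the Sras mutants was not shown by these values and stays open.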

How the results depend on the processing

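The values as deposited, the centring on identity genes and the WT baseline were chosen after the data were seen. All 16 counts stayed within 1.5 times the main count under the values as deposited, array-median centring, no filter and the mean of probe sets. No paired analysis was possible because each group holds 1 array. Leaving out replicates was not possible for the same reason, quantile normalization was already the main setting, and pseudocounts did not apply to log2 values. Counts below are given as higher and lower genes. Signal limits the dim genes: those near the filter value of 6.36 are measured close to background.

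Fewer genes are counted by construction under the stricter filter: Ras minus WT control gave 22 and 36, Sras mutant 1 minus Ras 183 and 361, Sras mutant 2 minus Ras 224 and 370, scrib minus Ras 462 and 591, both Sras mutants against Ras 166 and 327, both against scrib 345 and 180, and both with scrib against Ras 295 lower. A threshold of 1.5-fold gave 217 and 335 for Ras minus WT control, 1057, 1107 and 1733 higher for Sras mutant 1, Sras mutant 2 and scrib minus Ras, 66 and 141 between the Sras mutants, 886 higher in both than Ras, 896 and 721 against scrib, and 624 higher with scrib. At 3-fold these were 16 and 25 for Ras minus WT control, 91 and 439 for mutant 1, 136 and 479 for mutant 2, 269 higher for scrib, 3 and 16 between the Sras mutants, 82 and 405 for both against Ras, 278 and 120 for both against scrib, and 31 and 354 for both with scrib. With WT control as the baseline, 245 genes were higher in both Sras mutants and scrib, against 161 from Ras; the cause was not tested.

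Centring on the identity genes moved the median of all kept genes from 0.02 to −0.18 for Ras minus WT control, from 0.11 to −0.20 and from 0.08 to −0.46 for Sras mutants 1 and 2 minus Ras, from 0.12 to 0.91 for scrib minus Ras, from 0.02 to 0.25 between the Sras mutants, and to −1.12 and −1.37 for them minus scrib. Since so, eya, dac, dan and danr were themselves lower in scrib, the setting shifts the scrib array by construction. In the Sras arrays the retinal determination genes of the reference lay above Ras (medians of 1.26 and 1.18), so the setting subtracts part of that result from every other list there. Counts were 36 and 179 for Ras minus WT control, 160 higher for mutant 1, 146 and 1345 for mutant 2, 3496 and 700 for scrib, 32 and 26 between the Sras mutants, 116 higher in both, 121 and 4861 against scrib, and 102 higher with scrib. Among differences of the named genes of at least 2-fold, 13 changed sign, all against scrib; smaller ones were not followed here, and any positive difference of an Sras mutant from Ras smaller than the shift turns negative. For mutant 1 they became −0.046 in Ilp8, −0.11 in Sgs8, −0.014 in edl, −0.020 in Dad, −0.034 in ey and −0.075 in unc-13. For mutant 2 they became −0.043 in Obp56a, −0.16 in edl, −0.20 in Dad, −0.020 in Gal, −0.033 in pros, −0.076 in bt and −0.22 in Cpr49Ac.

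The same constant for every gene of an array cannot move a list's percentile, but it changed the sign of 55 of 143 medians that were set apart. In Ras minus WT control these became −0.053 for JNK, −0.019 for antennal and −0.018 for polarity genes. In Sras mutant 2 minus Ras they became −0.13 for JNK, −0.0087 for EGFR, −0.078 for Fanconi, −0.11 for DNA replication, −0.21 for mitosis, −0.16 for secreted factors, −0.14 for glutathione, −0.10 for unfolded protein response, −0.019 for ribosome biogenesis, −0.087 for photoreceptor and −0.072 for polarity genes. In scrib minus Ras they became 0.14 for Notch, 0.47 for lysosome, 0.51 for proteasome, 0.043 for ecdysone and 0.25 for hemocyte genes. In Sras mutant 1 minus scrib they became −0.58 for Notch, −0.26 for Wingless and Dpp, −0.92 for DNA replication, −0.53 for heat shock, −0.88 for proteasome, −0.28 for retinal determination, −0.77 for ecdysone, −0.83 for matrix, −0.77 for hemocyte, −0.73 for fat body, −0.21 for neuron and glia, −0.69 for muscle and −0.58 for salivary gland and gut genes. In Sras mutant 2 minus scrib they became −0.90 for JAK/STAT, −0.75 for Notch, −0.53 for Wingless and Dpp, −0.26 for heat shock, −1.13 for proteasome, −0.58 for retinal determination, −0.96 for antennal, −0.89 for ecdysone, −0.38 for fat body and −0.57 for neuron and glia genes. Between the Sras mutants they became 0.18 for JNK, 0.088 for JAK/STAT, 0.10 for Hippo, 0.16 for EGFR, 0.066 for secreted factors, 0.071 for antimicrobial, 0.13 for glutathione, 0.13 for unfolded protein response, 0.064 for glycolysis, 0.032 for antennal, 0.056 for ecdysone, 0.17 for cytoskeleton and 0.041 for fat body genes. The other settings changed the sign of 2 set-apart medians, by a change in the genes kept: −0.026 for salivary gland and gut genes in mutant 1 minus scrib with no filter, and 0.012 for secreted factors in Ras minus WT control with the stricter filter. Of the 143 calls, 5 were lost with the values as deposited, 5 with array-median centring, 7 with no filter, 11 with the stricter filter and 8 with the mean of probe sets, and 7, 7, 6, 6 and 5 were gained in the same order.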

Other observations

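Secreted factors differed among the tumors in ways not described above. The list of secreted growth and humoral factors was set apart in Sras mutant 2 (median 0.39 against Ras, and −0.16 after centring on the identity genes) but not in Sras mutant 1 (0.07) or scrib (−0.00086). Members went both ways in each: 8 of 21 were at least 2-fold higher and 5 lower in mutant 2, 5 and 5 in mutant 1, and 8 and 6 in scrib. In both Sras mutants 5 of its 21 genes were at least 2-fold higher than Ras and 4 lower, among the latter the chitinase-like genes Idgf1 (−2.51 and −2.53) and Idgf3 (−2.35 and −2.52). The matrix protease gene Mmp2 was above Ras in the Sras arrays (1.08 and 1.06) and below it in scrib (−1.34). In Ras against WT control the list had a median of −0.11 and was set apart downward, but its median was 0.01 under the stricter filter. It was also set apart downward in both Sras arrays against scrib (−0.25 and −0.31). The same held for mutant 1 against mutant 2 (−0.16, but 0.066 after centring on the identity genes).

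Antimicrobial peptide genes were set apart upward in scrib (median 0.80, with Drs at 1.74 and Mtk at 1.43) and not in the Sras arrays (−0.06 and −0.08) or in Ras against WT control (−0.19). Lysosome and beta-galactosidase genes, some of which are used as markers of senescence, lay below Ras in both Sras arrays (−0.17 and −0.18) and in scrib (−0.33, but 0.47 after centring on the identity genes), and in Ras against WT control their median was −0.06. The list was set apart downward in each of these comparisons, in Ras against WT control at the 1.91st percentile. The gene Gal itself, a beta-galactosidase, read −1.06 in Ras against WT control, −1.14 and −0.76 in the Sras arrays against Ras, and −2.08 in scrib. Cell cycle inhibitors were not set apart (4 kept genes, −0.10 in Ras against WT control, then 0.35, 0.35 and 0.34 against Ras in the Sras and scrib arrays), although trbl was higher by 1.05, 1.66 and 1.44. Sex-biased genes (3 kept) were not set apart in any of these comparisons (0.23, then −0.33, −0.39 and −0.41).

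The ecdysone synthesis gene spok read 12.09 in WT control, 11.28 in Ras, 8.85 and 7.34 in the Sras arrays and 4.97 in scrib. Like the markers of other larval tissues, it was high in WT control and Ras and lower in the mutant arrays. Whether its levels come from the discs or from other tissue was not tested, so they do not show a difference in ecdysone synthesis among the tumors.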
